A study of Mus musculus with 6 samples.

How the data were processed

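RNA was measured in sorted pro-B cells of mouse bone marrow in 4 libraries, 2 per genotype. Per the labels' protocols, total RNA of CD19+CD43+ cells was depleted of ribosomal RNA and made into libraries with a kit that marks strand by dUTP. The values are raw counts per gene as deposited by the authors, with no normalization. Per the submitters' processing notes, the tools were Trim Galore, HISAT2 2.2.0, SAMtools 1.10, deepTools 3.5.1 and featureCounts 2.0.0, and the genome build was GRCm38 (mm10). The strand setting, the treatment of reads that map to several places, and whether reads or fragments were counted are not stated in the sources used here, so overlapping, antisense and near-identical genes are uncertain. The deposited table also gives summed exon lengths in bp, per the file headers. A further 2 samples of merged reads repeat these libraries and were not used here.

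The table held 55335 genes with versioned Ensembl identifiers, of which 55154 matched a gene symbol by unversioned identifier and 181 did not. Every count column was assigned to its sample by the column name given in the labels. Biotypes, GC content and transcript lengths came from GENCODE M21, which is close to but not the release of the table. Totals ran from 10618925 to 12303429 counts per library, and a count of 0 allows at most 3 counts, between 0.250 and 0.283 CPM; intervals and floors of this kind cover counting error only. The 2 abundant transcripts Gm26917 and Gm42418 took between 17.6% and 24.6% of counts.

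The groups were compared with edgeR 4.0.16 in R 4.3.3: filterByExpr (minimum count 10), TMM factors, robust dispersion estimates, the robust quasi-likelihood F-test and Benjamini-Hochberg adjustment at 0.05. The dispersion handling was that of edgeR's newer method (legacy off), whereas the installed version uses the older handling by default; the older one was listed among the alternatives and called 117 genes, and the plan left the main setting implicit, so it was settled when both counts were known. Standard errors are the absolute log2 fold change divided by the square root of F. CPM use TMM-scaled library sizes, and all log2 fold changes are Cfp1-deleted against control. The common biological coefficient of variation was 20.4%. Every adjusted p is from edgeR for genes and, for lists, from camera of limma 3.58.1 on log-CPM (prior count 2) with a preset correlation of 0.01, two-sided, adjusted over the 28 lists with at least 3 tested members. Where a correlation estimated from these libraries is used instead, camera tests on the 2 residual degrees of freedom, so that hardly any list could pass.

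The test, apart from its dispersion setting, the alternatives in the next paragraph other than its last 4, 30 gene lists and the rule for named genes were fixed before the data were examined. The rule names Cxxc1, Rag1 and Cd79a; the 8 largest rises and 8 largest falls among changed genes with a mean logCPM of at least 2 and groups that do not overlap, without predicted genes, pseudogenes and receptor segments; 10 fixed B-cell genes (Ebf1, Pax5, Foxo1, Tcf3, Ikzf1, Rag2, Il7r, Vpreb1, Igll1, Cd19); and in each list up to 4 changed members with the smallest p, or the 1 with the smallest p where none changed. The lists cover B-cell identity, recombination, chromatin, other lineages, cell cycle, stress, metabolism, histones and immunoglobulin segments; counts of members are given over all genes and adjusted over the list alone. Of the tested genes, 48.8% had groups that do not overlap, where chance gives 33.3%.

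Alternatives were RLE, upper-quartile and plain library-size scaling, 2 other filters, DESeq2 1.42.0, limma-voom, non-robust and older dispersion handling, stricter thresholds, a replicate block, genes of odd RNA classes left out, and each library left out in turn. DESeq2 was run on the 25562 genes with any count, without the low-count filter, and limma-voom on the 14787 filtered genes. A further 4 were chosen after seeing the data: without Gm26917 and Gm42418, with a neutrophil granule covariate, and with Cxxc1 left out of the COMPASS list or the myeloid members Csf1r, Ccr2, Ccl9, Fcer1g and Cd33 left out of the Pax5-repressed list.

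The scripts were tested on simulated data: counts for the 14787 tested genes of Cfp1-deleted against control were drawn from the real means, dispersion trend and library sizes in 5 simulations, with 200 genes changed in each. EdgeR found 37.0% of the genes changed 2-fold and 85.8% of those changed 4-fold, and 5.10% of its calls were false. DESeq2 found 34.4% and 81.0%, and limma-voom 32.8% and 85.2%. Camera called the list that was made to fall in all 5 simulations and 0 of 250 unmoved lists. Simulated genes were independent of each other, which real genes are not.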

Results

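RNA was sequenced from sorted CD19+CD43+ pro-B cells of mouse bone marrow, the stage at which the immunoglobulin heavy chain locus is rearranged. All mice lacked Rag1, without which the locus is not cut and rearranged. The control group carried floxed alleles of Cfp1 and no Cre. The Cfp1-deleted group also carried Mb1-Cre, a Cre recombinase expressed from the Cd79a locus in early B-lineage cells. Cfp1, whose gene symbol is Cxxc1, is a CpG-binding subunit of the complexes that place trimethylation on lysine 4 of histone H3. Each group had 2 biological replicates. The libraries held 10618925 and 11344333 counts in the controls and 11820431 and 12303429 in the Cfp1-deleted group. In the series title the question is whether broad domains of this histone mark, kept by Cfp1, control early B-lineage fate.

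Cxxc1 itself was lower in both Cfp1-deleted libraries, at 25.1 and 29.8 CPM (TMM-normalised read counts) against 65.6 and 72.7 in the controls. Its log2 fold change was -1.33 (SE 0.15, n = 2 per group, adjusted p = 0.0343), which is 0.397 times the control level in counts over the whole gene. Cd79a, the gene in which Mb1-Cre sits, fell by 1.92 on the log2 scale (SE 0.24, adjusted p = 0.0450), with a 95% interval from -2.52 to -1.32. Only the Cfp1-deleted group carried Mb1-Cre. Effects of Cre, or of its insertion in Cd79a, therefore cannot be told apart from those of Cfp1 loss for any gene. Rag1 transcripts were counted in all libraries and did not pass the test (log2 fold change -0.59, SE 0.20, adjusted p = 0.227), and such counts do not check a disrupted allele.

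Dntt, which encodes the enzyme that adds nucleotides at V(D)J junctions, fell from a mean of 1305 CPM (SD 279) to 51.0 CPM (SD 7.23), a log2 fold change of -4.68 (SE 0.22, n = 2 per group, adjusted p = 0.00644). Igll1, a surrogate light chain gene, fell by 2.70 on the log2 scale (SE 0.17, adjusted p = 0.0136), and Il7r, the receptor chain for interleukin 7, by 1.76 (SE 0.22, adjusted p = 0.0401). Ly6a, which encodes the stem-cell antigen Sca-1, rose by 2.72 (SE 0.22, adjusted p = 0.0224), and Flt3, a cytokine receptor of lymphoid progenitors, by 1.45 (SE 0.15, adjusted p = 0.0310). Across 14787 tested genes, 148 changed in edgeR's quasi-likelihood test, 74 higher and 74 lower in the Cfp1-deleted group, and 126 of them changed at least 2-fold. The calls did not hold when either control was left out, and more genes were called when either Cfp1-deleted library was left out. With all libraries limma-voom called 17 of the same tested genes. DESeq2 called 555, from 25562 genes without the low-count filter, so that both tool and filter differ.

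Among changed genes with a mean logCPM of at least 2 that the naming rule admits, the falls with the greatest fold, after Dntt, were of Grb7 (log2 fold change -3.99, SE 0.30), an adaptor protein of receptor tyrosine kinases, and Cacna2d1 (-3.69, SE 0.27), a calcium channel subunit. Enpep (-3.56, SE 0.31), the cell-surface aminopeptidase known as BP-1, followed. Cacna1e (-3.41, SE 0.21), a pore-forming calcium channel subunit, went from 162 to 15.2 CPM. Serpina3n (-3.11, SE 0.37) and Slamf6 (-2.34, SE 0.23) completed the 8 largest falls by the naming rule, together with Igll1. Under the same limits the rises were led by Stum (log2 fold change 4.14, SE 0.33), which went from 0.907 to 16.2 CPM, and Tead2 (3.94, SE 0.50), a DNA-binding partner of YAP. Mn1 (3.76, SE 0.37), a transcriptional regulator of myeloid leukaemia, and Ly6c1 (3.49, SE 0.36), a surface antigen, came next. Rgs16 (3.22, SE 0.33), Prss23 (3.16, SE 0.40), Myo5c (3.08, SE 0.37) and Klrb1f (2.95, SE 0.40) were the rest of the 8 largest rises.

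**Figure D1:**
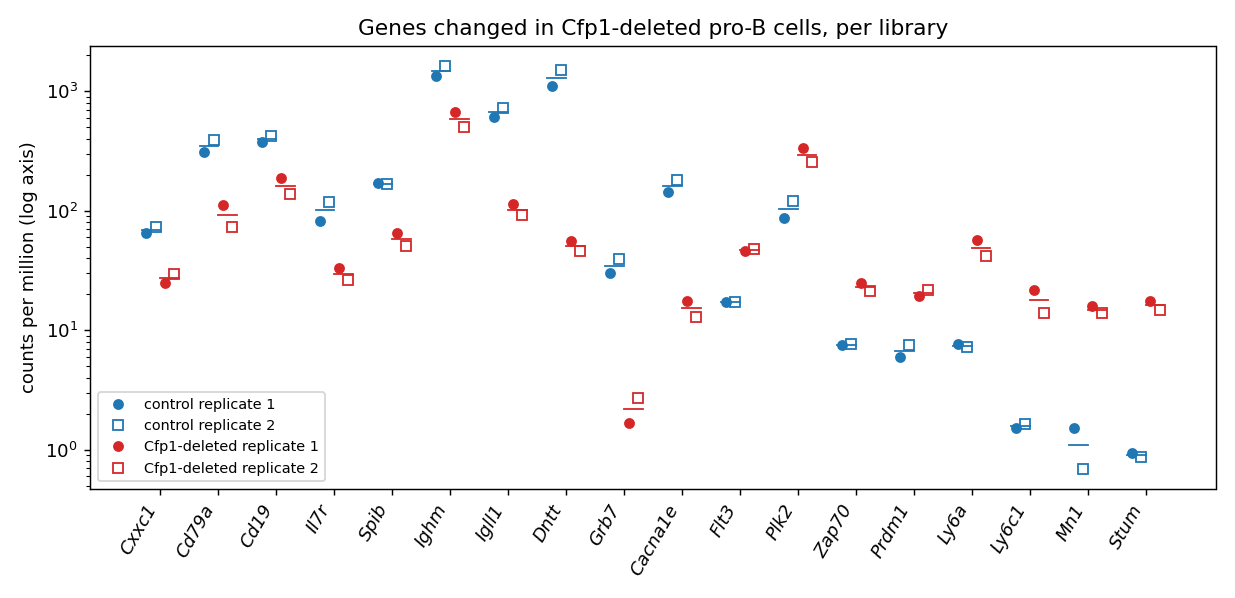
CPM (log axis) of 18 changed genes in each of the 4 libraries, with a horizontal line at each group's mean. Both Cfp1-deleted libraries lie on the same side of both controls for every gene drawn, as they do for all 148 changed genes.

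Among pre-BCR, surface and signalling genes of B cells, 5 of 30 tested members fell and 0 rose over all genes tested; adjusted over the list alone, 9 fell and 6 rose. The 5 were Cd79a and Igll1, given above, with Bst1 (log2 fold change -2.09, SE 0.24), Cd19 (-1.29, SE 0.18), the B-lineage surface molecule used in the sort, and Cd93 (-0.95, SE 0.13). Of these, Cd79a holds Mb1-Cre, and its fall cannot be told apart from an effect of that insertion. Vpreb1, the partner of Igll1 in the surrogate light chain, had a log2 fold change of -1.29 (SE 0.31) and did not pass (adjusted p = 0.156). As a set the list was not called by camera (adjusted p = 0.0967). It was called without control replicate 1 (adjusted p = 0.0312) and without Cfp1-deleted replicate 1 (adjusted p = 0.0344). Of 29 B-lineage transcription factors, 1 fell, Spib (-1.54, SE 0.15, adjusted p = 0.0310), an ETS factor; adjusted over the list alone, 4 fell. Ebf1 (-0.71, SE 0.21, adjusted p = 0.184) and Tcf3 (-0.54, SE 0.13, adjusted p = 0.136) did not pass. Pax5 (0.20, SE 0.16), Foxo1 (-0.07, SE 0.18) and Ikzf1 (0.03, SE 0.11) had intervals that include 0. The list's camera test gave an adjusted p of 0.0701, and 0.0420 without control replicate 1 and 0.00197 without Cfp1-deleted replicate 1. In the IL-7 receptor list Il7r alone changed among 21 members, 2 rose and 2 fell adjusted over the list alone, and the set was not called (adjusted p = 0.495).

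The list of V(D)J recombination and end-joining genes was lower as a set (camera adjusted p = 0.0207, and adjusted p = 0.527 with an estimated correlation). The value of 0.527 recurs for many lists below because the adjustment ties them. Their unadjusted p from camera with an estimated correlation ran from 0.0442 (later B-cell and antigen-presentation genes) to 0.282 (COMPASS and H3K4 demethylase genes). Dntt was the 1 member of 21 that fell; adjusted over the list alone 5 fell. Rag2 had a log2 fold change of 0.04 (SE 0.18). The set was not called without control replicate 2 (adjusted p = 0.107) or without Cfp1-deleted replicate 2 (adjusted p = 0.111). Immunoglobulin constant-region and J genes were lower too (9 tested, median -0.93 against a mean of -0.09, adjusted p = 0.0170, and adjusted p = 0.527 with an estimated correlation). Ighm, the constant region of the mu heavy chain, fell by 1.33 on the log2 scale (SE 0.19, adjusted p = 0.0447) and was the 1 member past the test over all genes, while 7 fell and 2 rose adjusted over the list alone.

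Unrearranged V segments of the heavy chain locus went the opposite way. Of 29 tested segments, 26 had a positive fold change, with a median log2 fold change of 1.70, and the set was higher (camera adjusted p = 4.29e-08, and adjusted p = 0.527 with an estimated correlation). No segment passed over all genes in edgeR, and 9 rose adjusted over the list alone. Ighv1-11, with the smallest p, had 2 and 0 counts in the controls and 43 and 18 in the Cfp1-deleted libraries (adjusted p = 0.0922). Igkv14-111 was the 1 light chain V segment with enough counts to test (log2 fold change -0.74, SE 0.52). V segments resemble each other in sequence, and how reads that map to several of them were counted is not stated in the sources used here, so that single segments are uncertain.

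**Figure D2:**
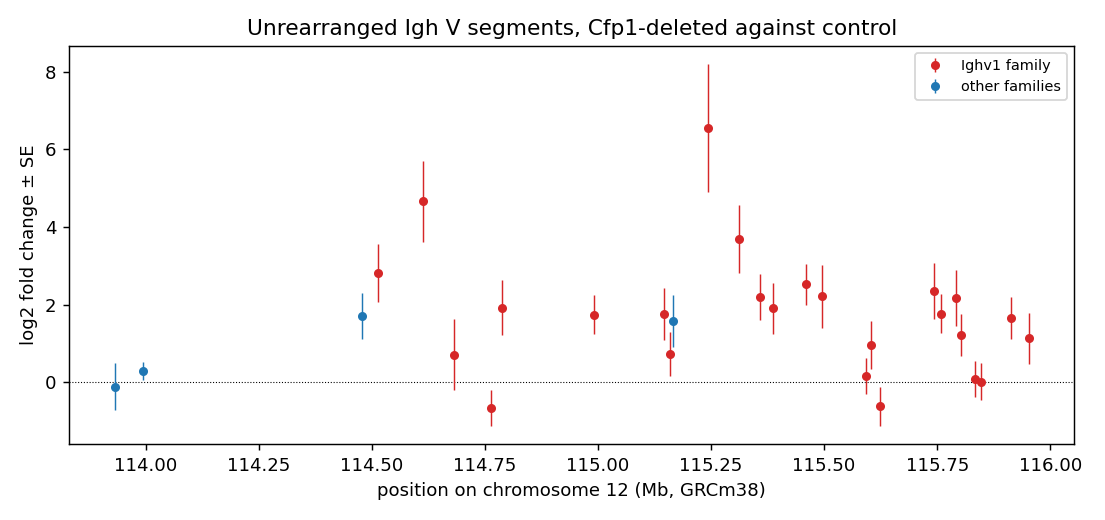
Log2 fold change with its standard error of the 29 tested heavy chain V segments against their position on chromosome 12 (Mb). Of these, 26 lie above 0.

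Replication-dependent histone genes were lower as a set. Of 65 tested, 64 had a negative fold change, with a median of -0.73 (camera adjusted p = 3.27e-25, and adjusted p = 0.527 with an estimated correlation). Over all genes 9 fell, and 59 fell adjusted over the list alone. Hist1h2bq (log2 fold change -1.88, SE 0.19), Hist1h2bf (-1.79, SE 0.21), Hist3h2ba (-1.68, SE 0.18) and Hist2h3b (-1.13, SE 0.13) had the smallest p; many of these genes are near-identical copies, so that single genes are uncertain. The cell-cycle list was lower as a set (median -0.44, adjusted p = 6.21e-06, and adjusted p = 0.527 with an estimated correlation). None of its 35 members passed over all genes in edgeR and 18 fell adjusted over the list alone; E2f2 had the smallest p (-0.83, SE 0.15, adjusted p = 0.0704).

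Chromatin lists moved by small amounts. The COMPASS and H3K4 demethylase list was lower (19 tested, median -0.13, adjusted p = 0.0134, and adjusted p = 0.527 with an estimated correlation), but Cxxc1 was the 1 member that fell, over all genes and adjusted over the list alone. With Cxxc1, the deleted gene, left out of the list, an alternative chosen after seeing the data, the other 18 had a median of -0.12 (adjusted p = 0.0384, and adjusted p = 0.660 with an estimated correlation). The list was not called without control replicate 2 (adjusted p = 0.0874) or without Cfp1-deleted replicate 2 (adjusted p = 0.200). Cohesin, CTCF and loop genes were lower (16 tested, median -0.25, adjusted p = 0.00218, and adjusted p = 0.527 with an estimated correlation), with 0 members past the test over all genes and 6 that fell adjusted over the list alone. Stag1 had the smallest p (-0.54, SE 0.11, adjusted p = 0.0934). DNA methylation genes were not called (15 tested, adjusted p = 0.577; Mbd4 log2 fold change -0.54, SE 0.16).

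Pax5-repressed genes were higher as a set (13 tested, median 0.60, adjusted p = 0.000119, and adjusted p = 0.527 with an estimated correlation), with 2 members that rose, Ly6a and Flt3, and 6 adjusted over the list alone. Its member Csf1r, a receptor of macrophages, stood at 76.1 and 114 CPM in the controls and 143 and 281 CPM in Cfp1-deleted replicates 1 and 2, and C1qa and Axl, given with the antigen-presentation genes, were also highest in Cfp1-deleted replicate 2. The list was called without Cfp1-deleted replicate 2 (adjusted p = 0.00295) and, in an alternative chosen after seeing the data, with its 5 myeloid members left out (8 tested, median 0.98, adjusted p = 2.02e-05, and adjusted p = 0.527 with an estimated correlation). T, NK and innate lymphoid genes were higher (24 tested, median 0.47, adjusted p = 0.00369, and adjusted p = 0.527 with an estimated correlation), with Zap70, a kinase of T-cell receptor signalling, as the 1 member that rose (1.60, SE 0.20, adjusted p = 0.0382); adjusted over the list alone 4 rose and 1 fell. This set was not called without control replicate 2 (adjusted p = 0.215), without Cfp1-deleted replicate 2 (adjusted p = 0.122) or with a mean of at least 50 counts (adjusted p = 0.0602). In the stem and progenitor list, Ly6a and Flt3 rose and Mllt3 fell (-0.997, SE 0.14), 4 rose and 1 fell adjusted over the list alone, and the set was not called (18 tested, adjusted p = 0.167, median -0.01 against a mean of 0.22). In the plasma-cell list Prdm1, a repressor of the B-cell program, rose (1.60, SE 0.23, adjusted p = 0.0465), 2 rose and 1 fell adjusted over the list alone, and camera did not call the 5 tested members (adjusted p = 0.577).

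Later B-cell and antigen-presentation genes were higher as a set (21 tested, median 1.02, adjusted p = 0.000140, and adjusted p = 0.527 with an estimated correlation). No member passed over all genes in edgeR and 5 rose adjusted over the list alone; H2-DMa, an MHC class II gene, had a log2 fold change of 1.17 (SE 0.18, adjusted p = 0.0501). Dendritic genes (11 tested, median 0.41, adjusted p = 0.0134, and adjusted p = 0.527 with an estimated correlation; Flt3 rose, 2 rose adjusted over the list alone) and interferon-response genes (28 tested, median 0.41, adjusted p = 0.00476, and adjusted p = 0.643 with an estimated correlation; 0 past the test, over all genes or adjusted over the list alone; Oas3 0.73, SE 0.17) were also higher. Macrophage genes moved with these groups in 1 library. C1qa stood at 106 and 134 CPM in the controls, 145 in Cfp1-deleted replicate 1 and 381 in Cfp1-deleted replicate 2, and Axl at 240 and 236, 264 and 863. Without Cfp1-deleted replicate 2 the antigen-presentation list was still called (adjusted p = 0.000368), and the dendritic (adjusted p = 0.489) and interferon-response (adjusted p = 0.180) lists were not. The dendritic list was also not called without control replicate 2 (adjusted p = 0.159), nor the interferon-response list without control replicate 1 (adjusted p = 0.130).

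**Figure D3:**
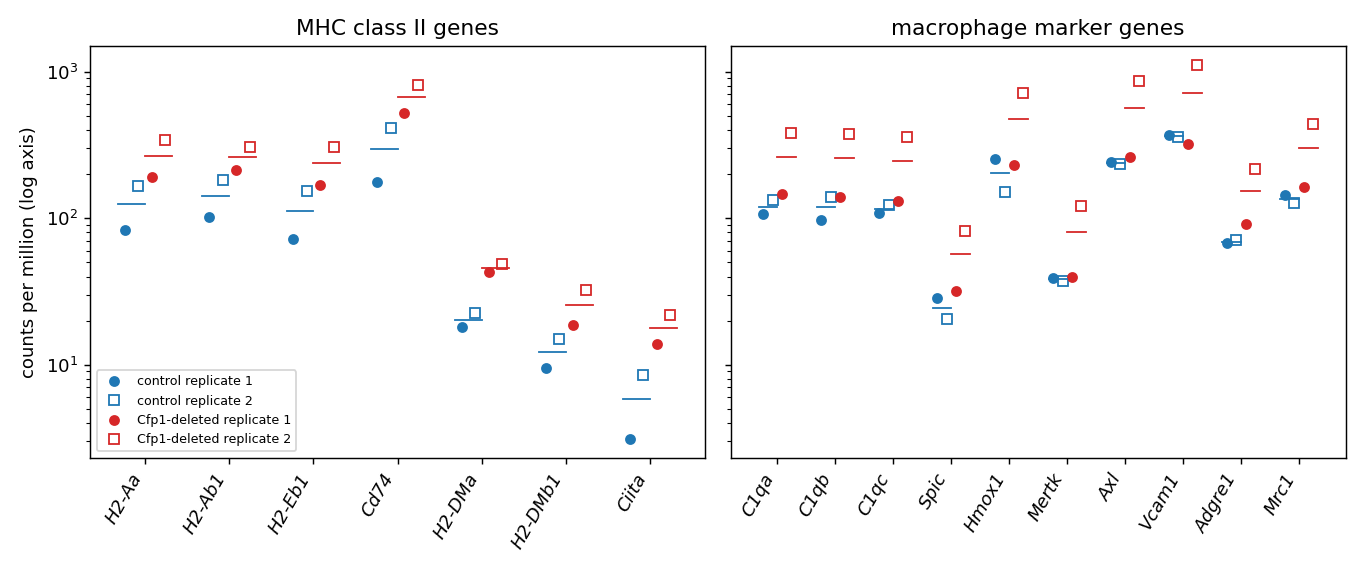
CPM (log axis) of 7 MHC class II genes and of 10 macrophage marker genes in each of the 4 libraries, with a horizontal line at each group's mean. The macrophage markers of Cfp1-deleted replicate 2 lie above the other libraries, and those of Cfp1-deleted replicate 1 lie near the controls.

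Myeloid genes were not called with all libraries (32 tested, adjusted p = 0.587; Csf1r 1.16, SE 0.39, adjusted p = 0.257), but the set was higher without Cfp1-deleted replicate 1 (adjusted p = 0.000510) and lower without Cfp1-deleted replicate 2 (adjusted p = 1.49e-07). Neutrophil granule genes took 0.874% and 0.651% of counts in the controls and 0.278% and 0.817% in the Cfp1-deleted libraries. Erythroid and megakaryocyte genes were not called (18 tested, adjusted p = 0.429; Klf1 -2.54, SE 0.94), and were lower without control replicate 2 (adjusted p = 0.00479) and without Cfp1-deleted replicate 2 (adjusted p = 0.0144). Stromal and endothelial genes were not called (14 tested, adjusted p = 0.138, 1 rose adjusted over the list alone; Runx2 1.29, SE 0.21, adjusted p = 0.0560).

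Genes of the p53 response were higher as a set (20 tested, median 0.46, adjusted p = 0.00393, and adjusted p = 0.527 with an estimated correlation). Plk2, a polo-like kinase, rose 2.82-fold (adjusted p = 0.0483), and 5 rose adjusted over the list alone. Of the 20 members, 15 had a positive log2 fold change and 5 a negative one, among them Mdm2 (-0.13, SE 0.11) and Trp53inp1 (-0.17, SE 0.14). Nr4a1, a nuclear receptor induced early by antigen receptor signals, rose (1.17, SE 0.17, adjusted p = 0.0495) in the immediate-early and stress list, of which 3 rose adjusted over the list alone; the set was not called (29 tested, adjusted p = 0.146), and was called higher without control replicate 2 (adjusted p = 0.00654). Apoptosis regulators (21 tested, adjusted p = 0.496; Birc3 -0.69, SE 0.14; 2 rose and 1 fell adjusted over the list alone) and glycolysis genes (19 tested, adjusted p = 0.667; Pfkp -0.69, SE 0.19) were not called. Homing and adhesion genes were not called (21 tested, adjusted p = 0.116; S1pr1 1.03, SE 0.16; 2 rose and 2 fell adjusted over the list alone), and were higher without control replicate 1 (adjusted p = 0.0393). Cytosolic ribosomal protein genes were not called (81 tested, adjusted p = 0.587; Rpl3l -1.41, SE 0.24), and were higher without Cfp1-deleted replicate 2 (adjusted p = 0.0144). Oxidative phosphorylation genes were not called (82 tested, adjusted p = 0.0701; Cox7a2 -0.46, SE 0.12), and were lower without Cfp1-deleted replicate 1 (adjusted p = 0.0101). Mitochondrially encoded genes had 0 counts in all libraries, so the deposited counts do not measure them and nothing can be read from this about their expression.

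**Figure D4:**
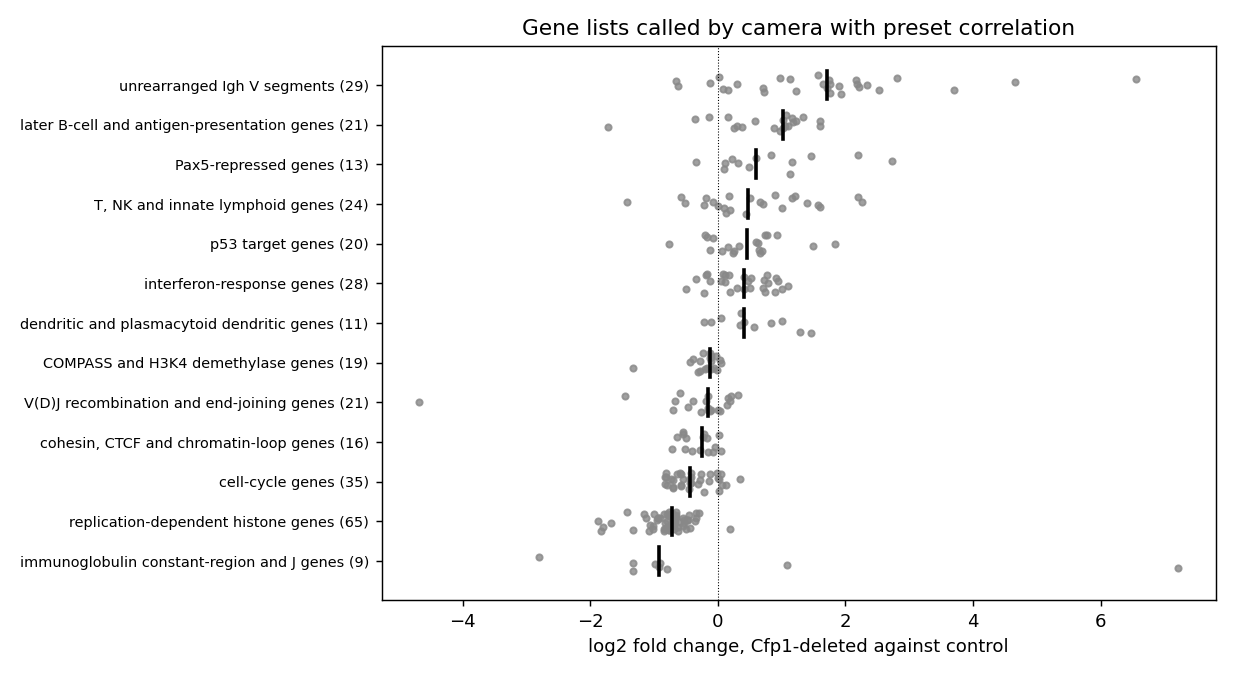
Log2 fold change of every tested member (points, spread vertically for legibility) of the 13 lists called by camera with its preset correlation, with a bar at each list's median. The number of tested members stands in brackets.

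Camera called 13 of the 28 lists with enough tested members, 7 higher and 6 lower, with its preset correlation of 0.01, and 0 with the correlation estimated from these libraries. With an estimated correlation the test rests on 2 residual degrees of freedom, where hardly any list could pass. The 0 calls therefore cannot decide whether the 13 hold. Fry, which asks whether a list's genes move one way without comparing them with other genes, called 1 (plasma-cell genes, adjusted p = 0.0175), and 21 changed in either direction.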

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

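All 148 calls kept their direction under every alternative in which they had a value. This says little about robustness, since the groups of all 148 do not overlap and a change of sign was hardly possible. The count and its split into higher and lower moved by less than 1.5 times with RLE factors, library size alone, upper-quartile factors (93 higher and 62 lower), no filter, older or non-robust dispersions, odd RNA classes left out, a 2-fold minimum, and Gm26917 and Gm42418 left out. A mean of at least 50 counts gave 69 genes (41 higher, 28 lower), DESeq2 555 (308 and 247, all 148 among them) and limma-voom 17 (6 and 11). An adjusted p of at most 0.01 left 1, Dntt (0 higher, 1 lower). The granule-gene covariate, chosen after seeing the data, gave 692 (416 higher, 276 lower). The cause of these differences was not tested. The gene sets differed as well: 10922 genes were tested with the stricter filter and 14787 by edgeR and limma-voom. DESeq2 was run on 25562 genes without the low-count filter, so its count reflects both tool and filter. The 2 Cfp1-deleted libraries differed more from each other (chi-squared per degree of freedom 25.9) than the 2 controls did (14.5). Pairs of different genotype ran from 27.2 (control replicate 2 and Cfp1-deleted replicate 1) to 42.3 (control replicate 2 and Cfp1-deleted replicate 2). The lowest of these is close to the Cfp1-deleted pair. Leaving out 1 library gave between 0 and 803 genes, 0 to 533 higher and 0 to 281 lower, with the lone library assumed to vary like the other group: 0 without control replicate 1, 0 without control replicate 2, 803 without Cfp1-deleted replicate 1 and 614 without Cfp1-deleted replicate 2. Camera called 13 lists, and 0 with an estimated correlation, where hardly any list could pass on 2 residual degrees of freedom. Fry called 1. With 2 libraries per group, genes changed 2-fold were found in 37.0% of simulated cases, so that a gene not called is not shown to be unchanged.

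The replicate numbers are shared between the groups, but the labels do not say that a number marks a litter or day, and the deviations of same-numbered libraries correlated at -0.162 across genes. With a replicate block edgeR called 0 genes (0 higher, 0 lower) with 1 residual degree of freedom, and 1906 genes had an unadjusted p under 0.05.

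Values that changed sign belong to results that were not called. The log2 fold change of Foxo1 ran from -0.33 without Cfp1-deleted replicate 1 to 0.17 without Cfp1-deleted replicate 2, and that of Rag2 -0.16 without control replicate 1. The list test turned direction for myeloid (adjusted p = 0.000510), glycolysis (adjusted p = 0.494), erythroid (adjusted p = 0.264) and ribosomal protein genes (adjusted p = 0.0603) without Cfp1-deleted replicate 1, and for erythroid (adjusted p = 0.439), immediate-early (adjusted p = 0.715) and ribosomal protein genes (adjusted p = 0.0823) without control replicate 1. With other libraries left out, the lowest adjusted p in the first direction was 1.49e-07 (myeloid), 0.188 (glycolysis) and 0.0144 (ribosomal protein) without Cfp1-deleted replicate 2, and 0.00479 (erythroid) and 0.00654 (immediate-early) without control replicate 2. The cause was not tested.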

Other observations

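All tests new to this part were chosen after the results were seen, except the match of histone genes to other genes by length, GC content and abundance. The gene calls, list tests and left-out libraries that it quotes were planned, apart from the dispersion setting. Their use to weigh explanations was not. The genes in this paragraph were picked from the changed genes after their values were seen, and no group was tested. Kcnh8 (log2 fold change -5.09, SE 0.86), a potassium channel, Trpa1 (-3.76, SE 0.55), a cation channel, and Scn4b (-1.36, SE 0.17), a sodium channel subunit, fell. Kcnh8 and Trpa1 lay under the naming rule's minimum mean logCPM of 2 and so are absent from the largest falls. Their folds rest on low counts. Scn11a (2.65, SE 0.35), another sodium channel, and Grik5 (1.67, SE 0.24), a glutamate receptor subunit, rose. Axin2, a target and inhibitor of Wnt signalling, fell by 2.33 on the log2 scale (SE 0.28). On the X chromosome 0 of 423 tested genes changed in edgeR, where 4.23 would be expected from the share over all genes. Within 5 Mb of Cd79a 1 of 130 tested genes changed, which was Grik5, and within 5 Mb of Cxxc1 0 of 35.

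The mean logCPM over all 4 libraries was 4.38 for the 74 higher and 5.90 for the 74 lower genes, a difference that 100000 permutations of direction across genes gave with p = 1e-05, the smallest they can give. Genes are not independent replicates, so the value describes these libraries. In the controls the median was 8.12 CPM for higher and 87.3 CPM for lower genes. Grouping genes by direction of change itself makes the gap wider in the controls, so its place there is not a separate result. In the Cfp1-deleted libraries the medians were 28.3 and 33.6 CPM.

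The antigen-presentation list was higher with the preset correlation (adjusted p = 0.527 with an estimated correlation), and macrophage RNA is a candidate source. The median log2 fold change of 14 macrophage markers was 1.14, against 1.10 for 7 MHC class II genes. Against the control mean the markers had a median log2 ratio of 0.25 in Cfp1-deleted replicate 1 and 1.68 in Cfp1-deleted replicate 2. The class II genes had 0.70 and 1.54, but the controls differ. In Cfp1-deleted replicate 1 the class II ratio was 1.24 to control replicate 1 and 0.32 to control replicate 2. The markers had 0.11 and 0.25 there. Vcam1, Axl and Hmox1 were the most abundant markers in Cfp1-deleted replicate 2 (1119, 863 and 718 CPM). Of the 14 markers, 2 (Vcam1 and Adgre1) also stand in the stromal or myeloid list. The sort for CD19+CD43+ cells is meant to leave out macrophages, but it does not argue against their RNA. The markers were counted in all libraries, with Vcam1 at 370 and 356 CPM in the controls. Without Cfp1-deleted replicate 2 the list was still called with the preset correlation (adjusted p = 0.000368), which argues against that library's macrophage RNA as the whole source, in a comparison that includes the low values of control replicate 1. Mature B cells are not expected by design, since all mice lacked Rag1. Igkc gave no sign of them, with a log2 fold change of -2.80 (95% interval -3.98 to -1.62). A part from macrophage RNA and a change within pro-B cells both stay open for the list.

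The rise of heavy chain V segments, called with the preset correlation (adjusted p = 0.527 with an estimated correlation), may reflect transcription of the unrearranged locus. B cells with rearranged loci are not expected by design, since all mice lacked Rag1. Igkc, with its log2 fold change of -2.80, gave no sign of RNA from such cells, although Igha had 0 CPM in the controls and 1.59 CPM in the Cfp1-deleted mean. The filter on low counts is argued against as well: of 103 segments with any count, 84.5% were higher in the Cfp1-deleted mean, and the sum without Ighv14-2 was 35.1 and 43.5 CPM in the controls and 137 and 63.8 CPM in the Cfp1-deleted libraries. A different heavy chain haplotype in the 2 groups of mice cannot be told apart from this, since a rise of 26 of 29 segments is allowed by it and the labels give no strain. Ighm fell while the V segments rose (log2 fold change -1.33, SE 0.19). That Ighm would follow the V segments under a haplotype cause was written only after the results were seen. Ighm can also change for reasons of its own, so its fall does not decide the question. Across segments, position on the chromosome and log2 fold change had a Spearman rho of -0.08 (permutation p = 0.694) and a Pearson r of -0.01.

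The fall of histone genes, called as a set with the preset correlation (adjusted p = 0.527 with an estimated correlation), may reflect fewer cycling cells or a change in histone genes themselves. The cell-cycle list had a median of -0.44, short of the histone median of -0.73, with overlapping quartiles, while 14 S-phase genes had a median of -0.0020 and quartiles of -0.58 and 0.05, which lie just above the histone quartiles of -0.90 and -0.63. By the bound first set for the S-phase genes this counts against fewer cells in S phase, but the bound was widened to the whole cell-cycle list after the result was seen, and with Rrm2 (-0.80), Tyms (-0.69) and Ccne2 (-0.82) near the histone median and the Mcm genes near 0, fewer cells in S phase cannot be told apart from a change specific to histones. Bias by length, GC content or abundance is argued against by 136 matched protein-coding genes (median -0.0293), but the match was loose (1349 against 534 bp), and 138 genes with transcripts under 900 bp and GC above 53% gave a median of -0.0136. The summed counts of all histone genes had a log2 ratio of -0.67 (18670 and 20240 CPM against 11480 and 13030). A mere exchange of reads between near-identical copies would leave this sum unchanged. The sum was taken after 64 of 65 tested genes were seen to be negative, so it restates that fall and is not a separate test.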
